A study of Thlaspi arvense with 10 samples.

How the data were processed

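RNA sequencing of poly(A)-selected RNA was available for 10 libraries of cultured pennycress embryos, 5 WT and 5 of the line that overexpresses WRI1 and DGAT1. Groups and replicate numbers were taken from the sample titles, and each column of the table was matched to its sample through the library name. The values deposited by the authors are raw counts per gene model, whole numbers that sum to a different total in each library, with no normalization. The submitters' processing notes name HISAT2 2.2.1, a read aligner, and StringTie 2.2.1, a transcript assembler, without their settings. The genome build, the annotation, the counting step and its strand setting are not given in the sources used here. The libraries were primed with random hexamers, per the labels' protocols, and no step that marks the strand is described there, so overlapping and antisense models may share reads.

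Among values from 1 to 12, multiples of 4 made up between 26.9% and 37.7% per library, where an even spread gives 25%. The deposited counts may thus hold several counts per sequenced fragment, which no source used here records, and counting intervals and floors are then too narrow. An alternative divided all counts by 4. Precision was judged from the spread between libraries and not from the counts, except for the ratios of the named models. Their floors and counting interval come from counts alone. The labels do not say whether the libraries of a group came from separate flasks or plants, so p-values measure the spread between these libraries, which may be technical.

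Models were kept by edgeR's filterByExpr, scaled by TMM and tested with the quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3), with the group as the single term and Benjamini-Hochberg adjustment over 17471 models. The threshold was an adjusted p of 0.05, with 2-fold as a second criterion. Standard errors of log2 changes were the log2 change divided by the square root of F. CPM in the text is counts scaled to the total of the whole library for MSTRG-numbered models named by identifier and for the on-or-off models, and TMM-scaled for the models ranked by abundance. Library measures were compared by two-sided exact permutation tests over all 252 assignments, with adjustment over 13 measures. The test was run on simulated data before use: counts were drawn for the 17471 models of the comparison of the line with WT, with 200 models changed, of which 92% of those changed 2-fold and 98% of those changed 4-fold were recovered, and 4.04% of the calls were false. The changed models were drawn from those with a mean of at least 5 CPM in WT, equally up and down. Far fewer models changed there than were called in the data, so these rates do not carry over to the reported calls.

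The test, the samples, the gene lists, the rule for named models and the main set of alternatives were fixed before the data were examined. Since the files do not pair identifiers with names or Arabidopsis loci and no annotation was used here, none of the members of the 20 fixed gene lists could be matched; the list tests and the tests of WRI1 and DGAT1 were not made. That also holds for the lists of seed coat and endosperm markers, so RNA from other seed tissues was not assessed. The rule for this case names the 2 models with the largest rise and the 2 with the largest fall among called models with a mean of at least 5 CPM and no overlap between the groups; other models are described by abundance rank. The ranking by abundance, the on-or-off models, the distances of libraries and the kinds of identifier were examined after the data had been seen.

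Pairs of libraries within a group were checked for duplicates by a chi-square on counts divided by 4, and the lowest of 20 pairs was 3.95 per degree of freedom, so no pair agreed within sampling noise. Alternatives used RLE and upper-quartile factors, scaling without the 100 most abundant models, no filter and a stricter filter, DESeq2 1.42.0, limma-voom (limma 3.58.1) with quality weights, a replicate block, each library left out in turn, and the locus-tagged models alone. Library totals alone, counts divided by 4, counts thinned to the smallest library of 55525341, and fits without WT libraries 1 and 3 or 2, 4 and 5 were added after seeing the data. Thinning drew single counts, so it removes too few fragments if 1 fragment is worth several counts. No column of the table was left unused.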

Results

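Poly(A) RNA was sequenced from cultured embryos of Thlaspi arvense (pennycress), an oilseed relative of Arabidopsis, of the cultivar Spring32. Embryos were taken from the pods about 15 days after flowering and kept for 10 days in a liquid medium with glucose, glutamine and alanine under continuous light, 15 embryos to a flask. Wild-type (WT) embryos were compared with embryos of line WD3, which overexpresses WRI1 and DGAT1. WRI1 is a transcription factor that activates genes of glycolysis and fatty acid synthesis in seeds, and DGAT1 is the enzyme that adds the last acyl chain in the making of triacylglycerol, the storage oil. Each group had 5 libraries. The WT libraries held between 68756445 and 89432933 counts each, and those of the overexpression line between 55525341 and 76983434. Counts were given for 27148 gene models, of which 6556 had a count of 0 in every library and 17471 had enough counts to be tested. The files do not pair the identifiers of these models with gene names, so levels of WRI1 and DGAT1 themselves, and of genes of oil, storage protein and sugar metabolism, are not reported here, and the labels of the line were not checked against its transgenes.

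The first question was how far the transcriptome of the line lay from that of WT. All 5 libraries of the line separated from all 5 WT libraries along the first principal component of log2 CPM, which held 68.6% of the variance, and the second component held 10.1%. Log2 CPM correlated across models with r between 0.864 and 0.902 for a WT library and a library of the line, between 0.945 and 0.981 within WT and between 0.973 and 0.981 within the line (models are not independent replicates). The mean distance of a library from the other 4 of its group was 0.556 ± 0.0956 log2 units in WT and 0.479 ± 0.0289 in the line (SD, n = 5 each), a difference within the spread of the libraries (two-sided exact permutation test, p = 0.143, adjusted p = 0.151 over 13 library measures). Without WT replicate 2, 4 or 5 the exact permutation p was 0.0159, 0.0159 and 0.0317. Without any other single library it lay between 0.175 and 0.452. Leaving out a WT library measures WT from a mean of fewer libraries than the line, which raises the WT distances. The distances in a group also share libraries, so all these p-values are approximate. On the second component WT replicates 1 and 3 had scores above 0 and WT replicates 2, 4 and 5 below 0. The libraries of the line lay between -15.015 and 8.86, a range that also held WT replicate 2, at -14.4.

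**Figure D1:**
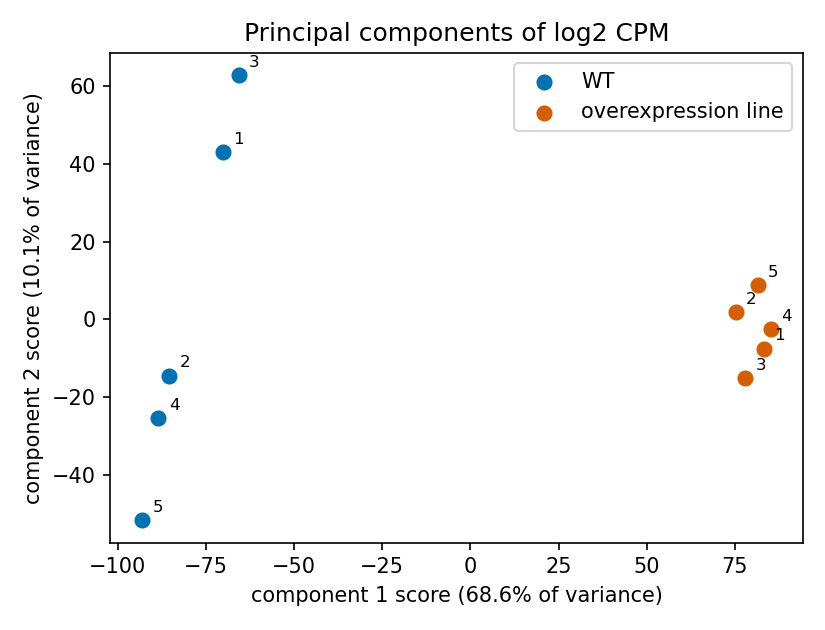
Scores of the 10 libraries on the first (x axis, 68.6% of variance) and second (y axis, 10.1%) principal components of log2 CPM, 1 point per library with its replicate number, coloured by group. The groups separate on the first component and the WT libraries spread along the second.

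Most of the transcriptome differed between the groups. Of the 17471 gene models tested, 11012 (63.0%) changed at an adjusted p under 0.05: 5173 rose and 5839 fell in the line, and 6459 did not pass (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5 libraries against 5). The median size of the change among the called models was 0.73 log2 units. The median standard error over all tested models was 0.12. Called models were picked for changes large against their error, so the contrast of these medians is no separate support. At least 2-fold changes were called for 3922 models, with 2148 higher and 1774 lower in the line, a balance that turned to 1805 and 2172 with upper-quartile factors. At least 4-fold, 728 models were higher and 636 lower, and at least 8-fold, 333 were higher and 242 lower. The CPM of the groups did not overlap in 8967 tested models (51.3%), where chance gives 0.794% for 5 libraries against 5. The balance of the directions depended on the scaling. Rising models made up 47.0% of the calls with TMM factors, 36.9% with upper-quartile factors and 62.7% with library totals alone, settings that moved the median log2 change over all models by -0.15 and 0.18 relative to TMM. Because the WT libraries fell into 2 sets on the second component, each set was also compared alone with the line, which called 10007 models against WT replicates 1 and 3 (5282 higher, 4725 lower) and 11709 against WT replicates 2, 4 and 5 (5902 higher, 5807 lower).

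**Figure D2:**
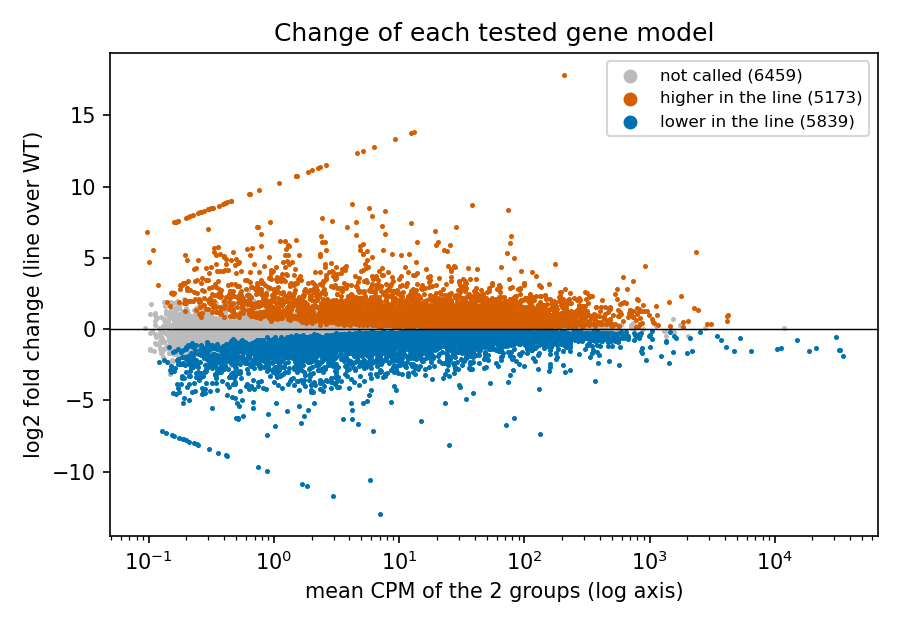
Log2 fold change of each of the 17471 tested gene models (y axis, line over WT) against the mean CPM of the groups (x axis, log scale), 1 point per model, coloured by whether it was called at an adjusted p under 0.05. Of the called models 5173 lie above 0 and 5839 below, with none above 0 among the 10 most abundant, and the straight lines of points at the upper and lower left are models at 0 in 1 group, whose fitted size depends on a small added count.

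The most abundant transcripts lost ground in the line. The 10 models with the largest mean CPM over all libraries held 28.9% ± 0.656 of the counts in WT and 14.1% ± 1.102 in the line (SD, n = 5 each), a difference of -14.8 percentage points. The model with the largest mean over all libraries held 5.13% ± 0.467 of the counts in WT and 1.57% ± 0.126 in the line, where the model of rank 4 held more, at 2.66% ± 0.259. The first 3 in this ranking together held 14.3% ± 0.440 and 5.34% ± 0.267. The first 100 held 42.3% ± 0.823 and 29.2% ± 1.21. Each of these 4 differences gave a two-sided exact permutation p of 0.00794, the smallest that 5 libraries against 5 allow, and an adjusted p of 0.0206 over the 13 measures. Of the 10 models, 9 fell and 1, the eighth in rank, was not called (log2 change 0.05, SE 0.19, edgeR adjusted p = 0.818); 9 fell and the eighth was not called under all 5 scalings tried (TMM, RLE and upper-quartile factors, scaling without the 100 most abundant models, and library totals alone). The largest fall among the 10 was that of the model of rank 1, at -1.89 log2 units (SE 0.11, edgeR adjusted p = 1.02e-07), or 3.71-fold lower in the line. The models of rank 2, 3 and 6 carry consecutive StringTie numbers and were lower by 2.77, 2.72 and 2.86 times. The fall was smaller for the models of rank 4 and 7, with log2 changes of -0.54 (SE 0.12) and -0.73 (SE 0.08). Whether reads are shared between such abundant models was not tested here.

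**Figure D3:**
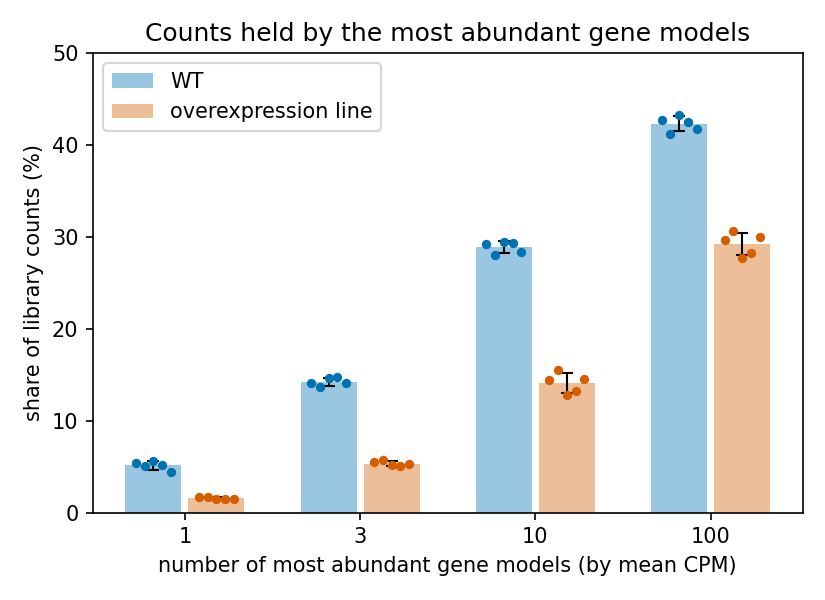
Share of library counts (y axis, %) held by the 1, 3, 10 and 100 gene models with the largest mean CPM over all libraries (x axis), for WT and the overexpression line. Bars are means, error bars the SD of 5 libraries and points single libraries; in each pair every library of the line lies below every WT library.

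Below the top of the range the directions were mixed. Among the models ranked 11 to 100 by abundance, 42 rose, 34 fell and 14 were not called. Here the largest rises were those of a model at 110 ± 6.75 CPM in WT and 4569 ± 270.3 CPM in the line (SD, n = 5 each), 41.7-fold higher (log2 change 5.38, SE 0.07), and of a model at 81.5 ± 2.84 CPM in WT and 1760 ± 163.0 CPM in the line, 21.6-fold higher (log2 change 4.43, SE 0.08). These models had the smallest and the second smallest p of all models tested, with edgeR adjusted p = 1.21e-11 and 6.82e-11. Of the 900 models ranked after these, down to rank 1000, 335 rose and 349 fell, and at least 2-fold changes were called upward in 153 and downward in 51. Of the 4000 models ranked 1001 to 5000, 1536 rose and 1256 fell, with 479 and 139 at least 2-fold. Among the 7471 tested models beyond rank 10000, 1660 rose and 2436 fell, with 1017 and 1322 at least 2-fold. Of the models ranked 5001 to 10000, 1600 rose and 1755 fell, with 481 and 242 at least 2-fold. The excess of at least 2-fold rises held under all 5 scalings in each range from rank 11 down to rank 10000. With upper-quartile factors it was small at ranks 5001 to 10000, 381 against 340. The majority of all calls did not hold: ranks 1001 to 5000 had 1202 rising and 1595 falling models with upper-quartile factors. Beyond rank 10000 the majority turned to rising models, 2036 against 1858, with library totals alone.

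**Figure D4:**
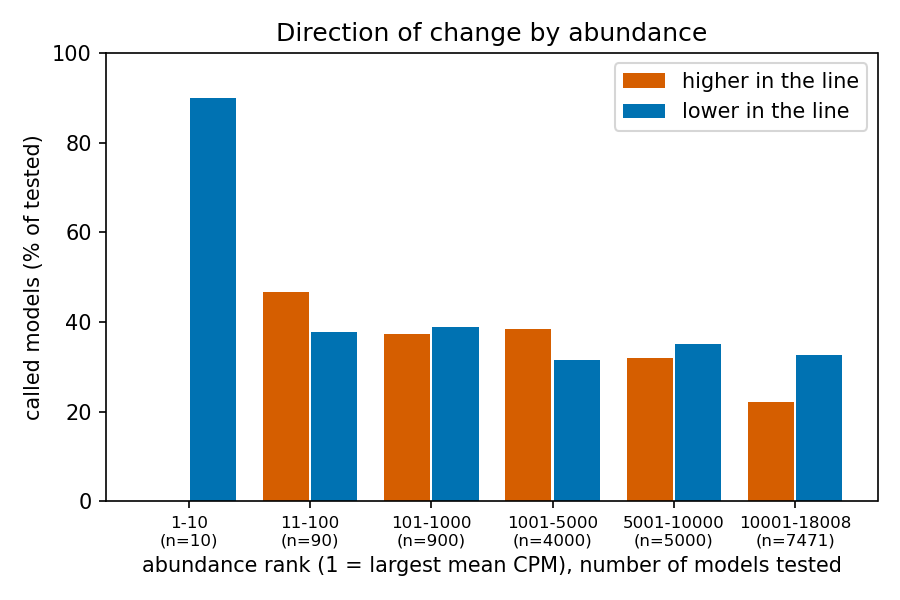
Percentage of tested gene models called higher or lower in the line (y axis) by rank of mean CPM over all libraries (x axis, number of models tested in brackets), with TMM scaling. Among the 10 most abundant models 90% were lower and none higher, while both directions occur in all other ranges.

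The models with the largest changes were counted in one group and nearly or wholly missing from the other. MSTRG.5481 stood at 443 ± 56.1 CPM in the line (SD, n = 5), with 21785 to 39924 counts per library, and had a count of 0 in all 5 WT libraries (edgeR adjusted p = 3.97e-09). Its mean CPM in the line was 10994 times the mean CPM of a floor of 3 counts per WT library. This is a ratio of means and not a lower bound. MSTRG.8171 stood at 27.8 ± 2.55 CPM in the line (SD, n = 5) and at 0 in all WT libraries (edgeR adjusted p = 1.15e-08). Its mean in the line was 691 times the same floor. MSTRG.12245 stood at 13.4 ± 1.77 CPM in WT (SD, n = 5) and at 0 in all libraries of the line (edgeR adjusted p = 1.72e-08). Its mean in WT was 286 times the floor of 3 counts per library of the line. MSTRG.1139 stood at 11.1 ± 1.43 CPM in WT (SD, n = 5) and had 2 counts in 1 library of the line and 0 in the other 4, a ratio of 1830 with an exact 95% counting interval from 506 to 15119 (edgeR adjusted p = 3.86e-09). This ratio rests on 2 counts in 1 library, below the floor of 3, so it cannot be set against the floor ratios of the other models. The floors and the counting interval cover counting error only. Low values pile up at multiples of 4, so that 1 fragment may stand for several counts. The floor of 3 is less than 1 fragment if fragments are worth 4 counts.

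Models counted in one group alone were found in both directions. A count of 0 in all WT libraries and at least 20 counts in every library of the line was found for 32 models, and the reverse for 11 models, a total of 43. No other split of the 10 libraries into 5 and 5 gave more than 2 such models, over all 126 splits. Every other split mixes the groups, so none of the 43 models could qualify there, and the contrast does not measure how unusual their number is. The 32 models had a median level of 1.98 CPM in the line, and the lowest stood at 0.522 CPM. The 11 models counted only in WT had a median level of 1.41 CPM there. A minimum of 40 counts left 19 and 9 models, and a minimum of 12 counts gave 41 and 20.

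The identifiers were of 3 kinds. Models numbered with the prefix MSTRG held 99.9% of the counts in both groups, and of 15751 tested, 4980 rose and 5429 fell, a balance that turned to 6484 and 3665 with library totals alone. Of 1539 tested models that carry a TAV2 locus tag, 187 rose, 373 fell and 979 were not called, with a median log2 change of -0.43. Falling models were the majority of these calls under all 5 scalings of the fit to all models. In a fit to the locus-tagged models alone, which scales them to each other, 217 rose and 165 fell. Of 181 tested models with the prefix STRG, 6 rose and 37 fell, with a median log2 change of -0.54, and falling models were the majority under all 5 scalings. The STRG models together held 0.0120% ± 0.00184 of the counts in WT and 0.00848% ± 0.000560 in the line (SD, n = 5 each; two-sided exact permutation p = 0.0159, adjusted p = 0.0344). The share of the locus-tagged models, 0.1000% ± 0.0132 in WT and 0.0903% ± 0.00254 in the line, did not differ by more than the spread of the libraries (exact permutation p = 0.151). Between 18174 and 18932 models had a count above 0 in the WT libraries and between 18153 and 18542 in those of the line, and after thinning all libraries to 55525341 counts the means were 18611 ± 289.1 and 18304 ± 167 (SD, n = 5 each; exact permutation p = 0.0714).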

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

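The tests of the scaling by abundant models, of library size behind the breadth of the change, of depth among the WT libraries and of other splits of the libraries for the numbers of calls were set before their results were seen; the others in this part were chosen afterwards. In 34 sets of 5 libraries checked for a value far from the other 4, 3 were found, where chance gives about 1 in 20. The distance of replicate 5 of the line from its group was 0.530 log2 units, against 0.457 to 0.474 for the other 4. MSTRG.1139 stood at 13.6 CPM in WT replicate 4 and at 10.04 to 11.01 CPM in the other WT libraries. The same model had 2 counts, 0.0359 CPM, in replicate 5 of the line and 0 in the other 4, which is less than 1 fragment if fragments are worth 4 counts.

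The breadth of the change, 11012 of 17471 models, was weighed against technical explanations. With scaling factors and library sizes that leave out the 100 most abundant models, 10949 models were called, 10810 of them shared with the main result. TMM factors already trim models at the ends of the abundance range, so this setting could move little and decides nothing by itself. With library totals alone, where abundant models do weigh in the scaling, 10704 models were called, 6716 higher and 3988 lower. The number of calls thus held without TMM, while the balance of the directions did not. After thinning every library to the smallest total, 10930 were called, which argues against library size as far as counts stand for fragments. Single counts were drawn, so if 1 fragment is worth several counts, a lower depth was imitated only in part. Among 100 of the 126 splits of the libraries, the real one included, only the real one gave as many calls. The highest of the others called 1 model. For at least 2-fold changes the real split called 3922 and the highest other 1. This share, 1 of 100, is the smallest these splits allow, and it argues against chance assignment of the libraries. Every other split mixes the groups, which adds their difference to the spread within each side, so the drop in calls does not measure its size. A difference between the groups in flask, day or harvest stays open, because no label records it (the stated ages, 15 days after flowering and 10 days in culture, are the same for all libraries), and so does the direct effect of the transgenes, which the design names and which was not separated from these.

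The second pattern is the set of 32 models counted in every library of the line and at 0 in WT. A difference in library size is argued against, since the WT libraries held on average 1.15 times the counts of those of the line. After thinning every library to the smallest total, 31 such models were found, 30 of them among the 32. A count of 0 in WT stays 0 when counts are removed, so only models near the minimum of 20 could drop out. That outcome was close to fixed and adds little to the comparison of totals. No other of the 126 splits of the thinned libraries gave more than 1 in either direction, but those splits mix the groups, so none of these models could qualify there. The thinning drew single counts, with the limit given above. A level in WT below the one that a count of 0 allows stays open; a comparison of the levels in the line with that level was also made and is left out, because the minimum of 20 counts fixes its outcome. Among the 32 were 26 with MSTRG numbers, of which 12 fell in 3 runs of consecutive numbers, with 5, 4 and 3 members, against a median of 0 and a maximum of 6 among 100000 random sets (permutation p = 1e-05, the smallest these draws can give). Of the 5 MSTRG models counted only in WT none fell in a run (permutation p = 1), too few to compare the directions. A candidate explanation is a genomic difference between the line and WT, such as an inserted sequence or another haplotype, that covers neighbouring models; a difference of haplotype would apply to both directions. It cannot be told apart from 1 transcript split over several models, since no source used here gives positions; the random sets also treat models as independent.

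The third pattern is within WT. Replicates 1 and 3 differed from each other by a chi-square per degree of freedom of 5.75, replicates 2, 4 and 5 by at most 13.8 among themselves, and the 2 sets by 28.6 to 65.1. Depth is argued against, because after thinning the lowest value between the sets was still 2.105 times the highest within them. The thinning drew single counts, but replicates 2 and 3, with near-equal totals of 68760277 and 68756445 before thinning, also differed by 34.0. An axis shared with the difference between WT and the line is argued against as the whole of it, since the leading WT component and the log2 change correlated across models with an absolute r of 0.16. The sets did part on the first component of all libraries as well, where replicates 1 and 3, at -70.2 and -65.7, lay nearer the line than replicates 2, 4 and 5, at -85.5, -88.4 and -93.1, so a part along that axis stays open. Their TMM factors parted too, 0.897 and 0.872 against 0.963 to 0.988, with replicates 1 and 3 the farther from the line, at 1.044 to 1.085. A preparation batch may lie behind it and stays open, because the labels record none, and so does an actual difference in stage between embryos of the same stated age; the fit without WT libraries 1 and 3 called 11709 models and the fit without WT libraries 2, 4 and 5 called 10007.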

How the results depend on the processing

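The alternatives of library totals, counts divided by 4, thinning and the sets of WT libraries, and all those for abundant shares, on-or-off models and distances, were chosen after seeing the data. The count of called models stayed between 10007 and 12108 and that of at least 2-fold changes between 3139 and 4700 under every alternative but one. Restricted to locus-tagged models, which hold about 0.1% of the counts, the fit called 382 models and 353 at least 2-fold, where the fit to all models called 187 of these higher and 373 lower; both the models tested and their scaling differed, and the cause was not tested. Leaving out each library in turn gave 10208 to 11152 calls, and 3793 to 4273 at least 2-fold. The replicate numbers did not pair the libraries, with correlations of deviations between -0.16 and 0.02; the replicate block gave 10399 calls and 3965 at least 2-fold. Limma-voom called 12108, DESeq2 11456 and the fit to counts divided by 4 called 10691. The 4 named models kept their direction and call in all 92 values under alternatives, with a highest adjusted p of 0.000487 over edgeR, DESeq2 and limma. They were chosen from these data for large changes without overlap, so this outcome was close to fixed. The fitted log2 change without 1 library ranged from 17.74 to 17.90 for MSTRG.5481. It was 15.83 with counts divided by 4 and 15.87 with limma-voom, since the size for a group at 0 depends on a small added count. For MSTRG.1139 the fitted change without 1 library ranged from -12.72 to -10.29, and its size depends on the 2 counts in replicate 5 of the line. The difference in the share of the 10 most abundant models lay between -15.1 and -14.5 percentage points without 1 library and was -14.8 with each library's own 10. The on-or-off models numbered 33 to 36 in the line and 11 to 15 in WT without 1 library. Leaving out a library only drops a condition, so these numbers could not fall and do not test the result. At a minimum of 40 counts 19 were left in the line, and 20 were found in WT at a minimum of 12, since the minimum sets how many qualify. The ratio of distances, WT over the line, was 1.16, between 1.099 and 1.274 without 1 library and 1.205 after thinning. Leaving out a library measures its group from a mean of fewer libraries, which raises the distances in that group. Thinning to the smallest library left 31 on-or-off models in the line and 10 in WT; at this depth 20 counts may be as few as 5 fragments. The tests of gene lists, WRI1 and DGAT1, and their alternatives, were not run, because no identifier could be matched to them.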

Other observations

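The 5 models with MSTRG numbers next to another among the 12 most abundant belong to 2 sets of consecutive numbers, and all 5 fell in the line. The models of rank 5 and 11 carry consecutive numbers and had log2 changes of -1.34 (SE 0.13) and -1.54 (SE 0.18). The eighth model in abundance rank was the 1 among the 12 that was not called, at 1.09% ± 0.280 of the counts in WT and 1.29% ± 0.106 in the line (SD, n = 5 each).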
